A study of Mus musculus with 2 samples.

How the data were processed

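Klf4 chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on mesenteric arcades of C57BL/6 mice. Per the labels, 1 library came from mice with intact Klf4 and 1 from mice in which Klf4 was deleted in smooth muscle cells (SMC), both kept on chow diet. The genotypes are given as eYFP+/+ Klf4WT/WT and eYFP+/+ Klf4delta/delta. Per the labels' protocols, the stromal vascular fraction of frozen, ground tissue was fixed with paraformaldehyde, sonicated and precipitated with an anti-Klf4 antibody, and libraries followed Illumina's TruSeq DNA protocol. The labels describe the material as a mixture of smooth muscle, epithelial, macrophage and other cells, so a peak is not tied to a cell type.

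The deposited data used here are 1 peak list for the whole series, which gives for each peak a chromosome, a start, an end, a name and a score assigned by the authors' peak caller. Peak names begin with MACS in the file, so peaks were called with MACS, whose version and threshold are not given in the sources used here. Bowtie, SAMtools and the genome build mm9 are named in the submitters' processing notes, without versions. The list names no genotype. Which library entered peak calling as the ChIP sample, and whether the other served as its control, is not given in the sources used here, so wild-type and Klf4-deleted tissue were not compared. Peaks were analysed as 1 set with no replicate error, and the intervals below cover counting error only. The read depth of the libraries is not given in the sources used here.

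Starts were shifted by 1 base so that coordinates are 1-based. All coordinates are in mm9. The gene table used here belongs to another assembly (GRCm38.p6), and coordinates were not moved between builds. Peaks were therefore not assigned to genes, promoters, exons or introns, sequence motifs were not searched, and the 17 gene lists fixed before the data were examined were not tested. From that table only the number of protein-coding genes on each chromosome was taken, 21627 over the autosomes and chromosome X. Chromosome lengths of mm9 were not used here. The span from the first to the last peak of a chromosome stood in for its length, which understates the length where its ends hold no peak.

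Counts per chromosome were compared with the shares of span and of protein-coding genes by two-sided exact binomial tests with Benjamini-Hochberg adjustment over 20 chromosomes. Rates carry exact Poisson 95% intervals and the X-to-autosome ratio an exact (Clopper-Pearson) 95% interval. Relations over the 19 autosomes were tested with 100000 permutations, 4 relations in all. A cluster was defined as at least 3 peak midpoints within 50 kb, with windows sharing a peak joined. Clusters and gaps under 1 kb were compared with 1000 random placements of the same number of peaks per chromosome, uniform over its span or within each peak's own 1 Mb bin, in one-sided permutation tests. Peaks near each other are not independent, which makes the p-values of all tests over peaks too small. Adding 200 planted clusters to simulated uniform peaks raised the cluster number by 198. Of 20 uniform sets, 1 gave p at or under 0.05 in the test by uniform placement. Both outcomes follow from how the peaks were simulated, so they check the computation only and not the placement within 1 Mb bins.

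The scores were compared, to 2 decimals, with -10 log10 of the Poisson probability of more than k events at backgrounds of 1, 2, 3 and 4, and with the same backgrounds shifted by 0.1 to 0.9. This tested whether the authors' score behaves as a Poisson p-value, since the file has no header.

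The peaks named were chosen before the data were examined, as the 10 with the highest score and the 3 densest clusters, with ties ordered by coordinate. The part of that rule that names genes could not be applied. The alternatives tried were the upper 50% and upper 25% of scores, merging of overlapping or close peaks, cluster windows of 10 kb and 100 kb, and ranking by width or score per kb. The use of spans, gene numbers, 1 Mb bins and merging under 1 kb was chosen after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.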

Results

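Occupancy of Klf4, a zinc-finger transcription factor, was profiled at baseline in the mesenteric microvasculature of mice, in 1 library with intact Klf4 and 1 library with Klf4 deleted in SMC. A single set of 7313 peaks was examined, whose names ran from 1 to 7313 without a gap. Klf4 peaks here means peaks of this list, whose dependence on Klf4 was not tested, since genotypes were not compared and motifs not searched. Klf4 peaks were found on each of the 19 autosomes and on chromosome X, and 15 peaks lay on sequences not placed on a chromosome. The set covered 7.27 Mb of mm9, and no neighbouring peaks overlapped.

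Most Klf4 peaks were about 1 kb wide. The median width was 913 bp, with quartiles of 698 and 1203 bp and a range of 225 to 4669 bp, and 199 peaks reached 2000 bp. The score had a median of 112.02 and a range of 60.01 to 1023.8, and 12.3% of peaks scored under 70. Scores above 500 were reached by 35 peaks, or 0.479% of the set. Wider peaks scored higher across peaks (Spearman's rho = 0.55), with rho between 0.48 and 0.62 within each of 20 chromosomes. Peaks are not independent replicates, so no p-value was attached to this relation.

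Part of the scores fell on fixed steps. Of all scores, 20.9% (1528 peaks) equalled, to 2 decimals, -10 log10 of the Poisson probability of more than k events at a background of exactly 1, 2, 3 or 4. Backgrounds shifted by 0.1 to 0.9 matched between 0.287% and 0.533% of scores. At a background of 1, 793 peaks matched, with a median k of 12 and a range of 9 to 48. At a background of 2, 431 peaks matched, with a median k of 17. The commonest score, 90.8, was shared by 160 peaks and corresponds to a k of 11 at a background of 1. The remaining scores did not match these steps, and no k was assigned to them. Reading k as a number of tags would assume a background in whole tags, with no scaling between libraries for depth, which the sources used here do not state. The uneven number of peaks over k, given under other observations, speaks against that reading.

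**Figure D1:**
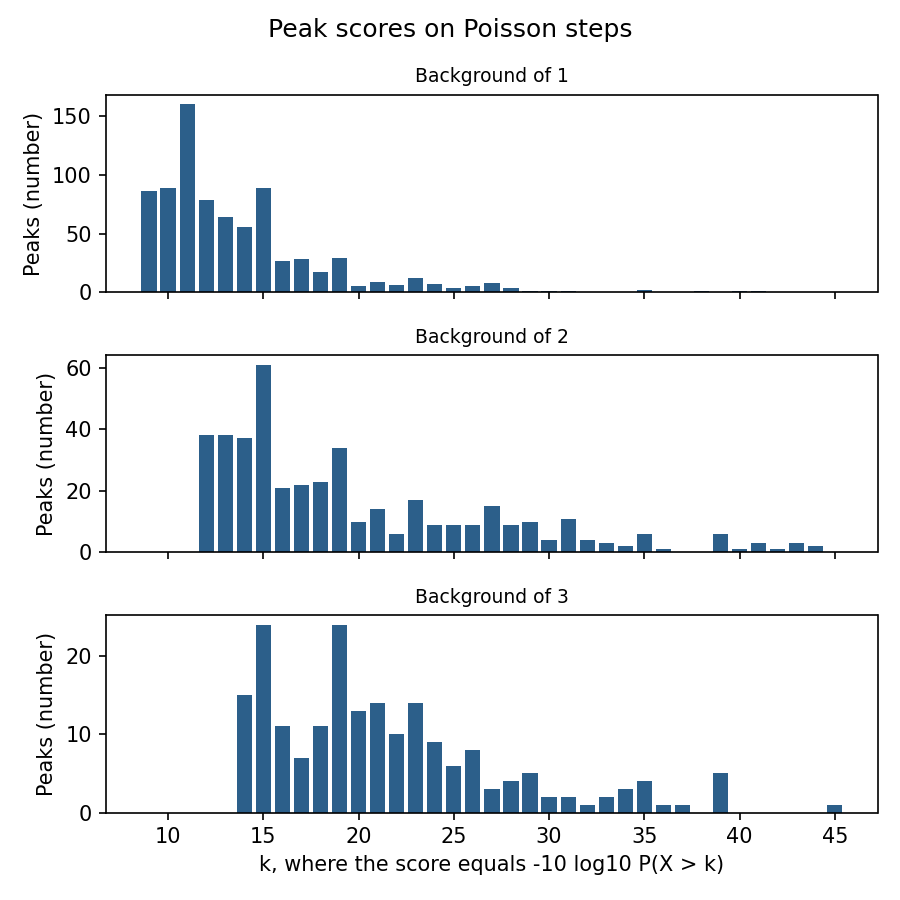
Number of peaks (vertical axis) whose score equals -10 log10 P(X > k), against k (horizontal axis, up to 45), for backgrounds of 1, 2 and 3 (panels from top to bottom). At a background of 1 the tallest bar is at a k of 11, with 160 peaks.

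The 10 peaks with the highest scores lay on 8 chromosomes. The highest score, 1023.8, belonged to a 2041 bp peak on chromosome 8 at 20018833 to 20020873. A peak with a score of 1010.6 followed on chromosome 10 at 96079721 to 96083978, and it was also the peak ranked 2 by width, with 4258 bp. Chromosome 16 held a peak with a score of 944.53 at 55819213 to 55823297. Chromosome 19 held one with a score of 876.24 at 5798480 to 5802629, and chromosome 9 one with a score of 834.03 at 44411732 to 44414335. The peak ranked 6, with a score of 799.01, lay on chromosome 8 at 19784192 to 19785985, on the same chromosome as the highest peak of the set. Ranks 7 to 10 were held by a peak on chromosome 13 at 37918044 to 37920190 (score 735.85), one on chromosome 11 at 70465944 to 70468225 (score 656.95), one on chromosome 10 at 98724646 to 98729314 (score 639.28) and one on chromosome 14 at 26278421 to 26281350 (score 638.78). The chromosome 10 peak at rank 9 was the widest of all, at 4669 bp. Only 4 of these 10 peaks were also among the 10 widest, and 1 was among the 10 with the highest score per kb.

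Klf4 peaks were most frequent on chromosomes 11, 19 and 17 and least frequent on chromosome X. Chromosome 11 held 617 peaks, or 5.21 per Mb of span (95% interval 4.81 to 5.64). Chromosome 19 held 275 peaks, or 4.74 per Mb (4.20 to 5.34), and chromosome 17 held 363 peaks, or 3.94 per Mb (3.54 to 4.36). The sparsest autosome was chromosome 1, with 412 peaks and 2.14 per Mb (1.94 to 2.36). Chromosome X held 130 peaks, or 0.817 per Mb (0.683 to 0.970). Relative to the span of each chromosome, 7 of 20 chromosomes held more peaks than expected, 7 held fewer and 6 did not pass the threshold (two-sided exact binomial test, Benjamini-Hochberg adjusted). These expectations include chromosome X, whose low count leaves the autosomes together above expectation, so calls near the threshold may depend on chromosome X. Chromosome 11 had an adjusted p = 4.42e-43 in the exact test, with 617 peaks against 339.2 expected. Chromosome X had an adjusted p = 2.18e-74 in the exact test, with 130 peaks against 455.5 expected.

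The number of peaks on an autosome rose with its number of protein-coding genes. Over the 19 autosomes, Pearson's r was 0.93 and Spearman's rho 0.95 (both permutation p = 1e-05, the smallest that the permutations can give, adjusted p = 1.3e-05). Without the 2 autosomes farthest from the median gene number, r was 0.95. The relation with span was weaker in value, with r = 0.62 (permutation p = 0.0046) and rho = 0.73 (permutation p = 0.0006), and with r = 0.68 without the 2 autosomes farthest from the median span. The difference between the relations was not tested. Peaks per Mb and genes per Mb were related with r = 0.89 and rho = 0.90 (both permutation p = 1e-05), and with r = 0.93 without the 2 autosomes of most extreme gene density. Both rates are divided by the same span, which permuting the finished rates does not reproduce, so these p-values may be too small. Per 1000 protein-coding genes, autosomes held between 261.1 peaks (chromosome 7) and 418.3 peaks (chromosome 12). Against the share of genes, 5 chromosomes held more peaks than expected, 2 held fewer and 13 did not pass the threshold. The 5 were chromosomes 5, 11, 12, 18 and 19, and the 2 were chromosomes 7 and X. These expectations also include chromosome X, and chromosome 19 lay near the threshold (275 peaks against 237.9 expected, adjusted p = 0.046, exact binomial test). Chromosome 7 held 530 peaks against 685.0 expected (adjusted p = 1.28e-09, exact binomial test).

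**Figure D2:**
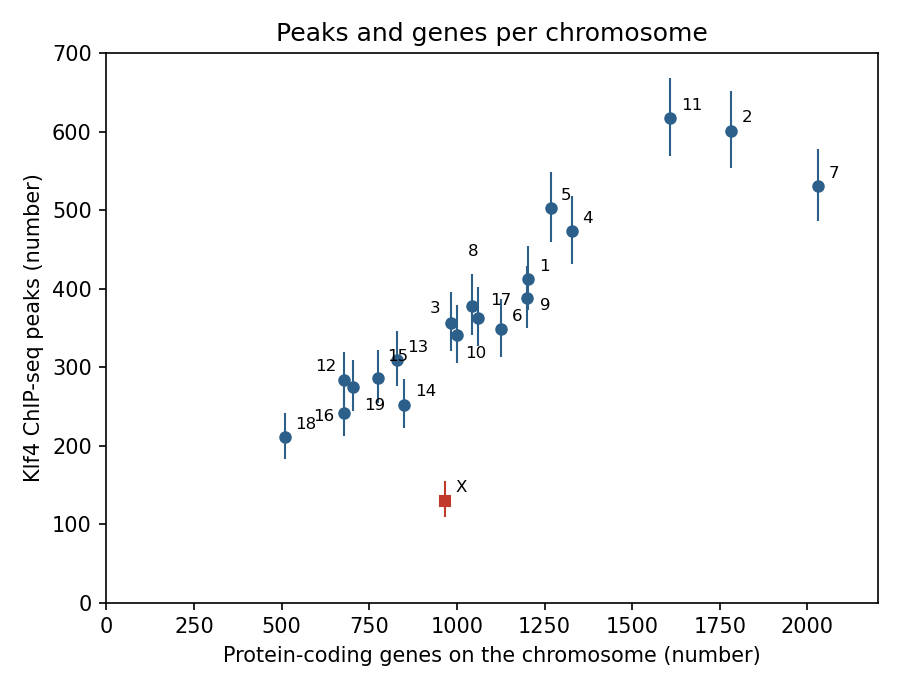
Number of Klf4 ChIP-seq peaks (vertical axis) against the number of protein-coding genes (horizontal axis) for the 19 autosomes (blue circles) and chromosome X (red square). Bars are exact Poisson 95% intervals of the count. Chromosome X, with 130 peaks, lies below all autosomes, and chromosome 11, with 617 peaks, lies at the top.

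Chromosome X stood apart in number and in score of its peaks. Its peaks per Mb came to 0.272 times the value of the autosomes (95% interval 0.227 to 0.324), and its peaks per protein-coding gene to 0.388 times (0.324 to 0.461). The median score on X was 87.7 against 112.29 on the autosomes, a difference of -24.6 (two-sided permutation p = 0.0004). Medians of the 19 autosomes ranged from 103.0 on chromosome 7 to 120.1 on chromosome 16, and all were above that of X. The median width on X was 706.5 bp against 916 bp on the autosomes. The highest score on X was 341.3. Among the upper 50% of scores the ratio per Mb was 0.154 (0.108 to 0.213), and among the upper 25% it was 0.0828 (0.0396 to 0.153).

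Klf4 peaks were unevenly spread within chromosomes. Of 2568 bins of 1 Mb, 864 (33.6%) held no peak, while 160 bins (6.23%) with at least 10 peaks held 29.8% of all placed peaks. The fullest bin, with 25 peaks, was at 52 to 53 Mb on chromosome 7. Bins with 24 peaks each lay at 5 to 6 Mb on chromosome 19 and at 108 to 109 Mb on chromosome 9. The longest stretch without a peak, 20.8 Mb, lay on chromosome X between 110299166 and 131116955. It was followed by 19.5 Mb on chromosome 14 between 79988129 and 99444387. Of the 10 longest such stretches, 3 were on chromosome X. Assembly gaps and regions where reads do not map uniquely were not separated from these stretches.

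Clusters of at least 3 peaks within 50 kb numbered 418 and held 1583 peaks, or 21.7% of those placed. Uniform placement gave 76.4 clusters on average and 106 at most (one-sided permutation test by random placement, p = 0.001, the smallest that 1000 placements can give). Placement within 1 Mb bins gave 272.3 on average and 309 at most (permutation p = 0.001). When peaks under 1 kb apart were merged first, there were 251 clusters, against 218.2 on average and 252 at most within 1 Mb bins (permutation p = 0.003). The redrawn positions were not merged in turn. Random sets could therefore hold neighbours under 1 kb apart, which the merged set could not. This can raise the random cluster numbers, so the size of the excess after merging was not measured like for like. The densest clusters each had 7 peaks within 50 kb. They lay on chromosome 3 at 96000946 to 96078382 (9 peaks, scores 60.46 to 211.76), on chromosome 17 at 34046179 to 34092598 (7 peaks, scores 62.19 to 188.16) and on chromosome 17 at 35958634 to 36056065 (11 peaks, scores 63.35 to 181.73). With peaks under 1 kb apart merged, these clusters held 6, 5 and 8 regions, in the order given. The cluster with the most peaks, chosen after its values were seen, held 21 peaks over 278.2 kb on chromosome 19 at 8787269 to 9065515. After the same merging it held 18 regions.

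Neighbouring peaks were separated by a median of 94.1 kb, and many were much closer. Of 7278 gaps between neighbours, 619 (8.51%) were under 1 kb, with a median of 168 bp. Uniform placement gave 45.5 pairs under 1 kb apart or overlapping on average and 70 at most, and placement within 1 Mb bins 96.2 on average and 124 at most (both one-sided permutation p = 0.001, the smallest that 1000 placements can give). Overlapping pairs were counted in these random numbers, although no neighbouring peaks of the list overlapped. The random numbers thus overstate gaps under 1 kb. Gaps under 250 bp numbered 422, gaps of 250 to 500 bp 128, and gaps of 500 to 1000 bp 69. Between 1000 and 2000 bp there were 46. The 1209 peaks with a neighbour under 1 kb away had a median width of 776 bp against 942 bp for the others, and a median score of 99.4 against 113.45 (both permutation p = 1e-05, the smallest that the permutations can give).

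**Figure D3:**
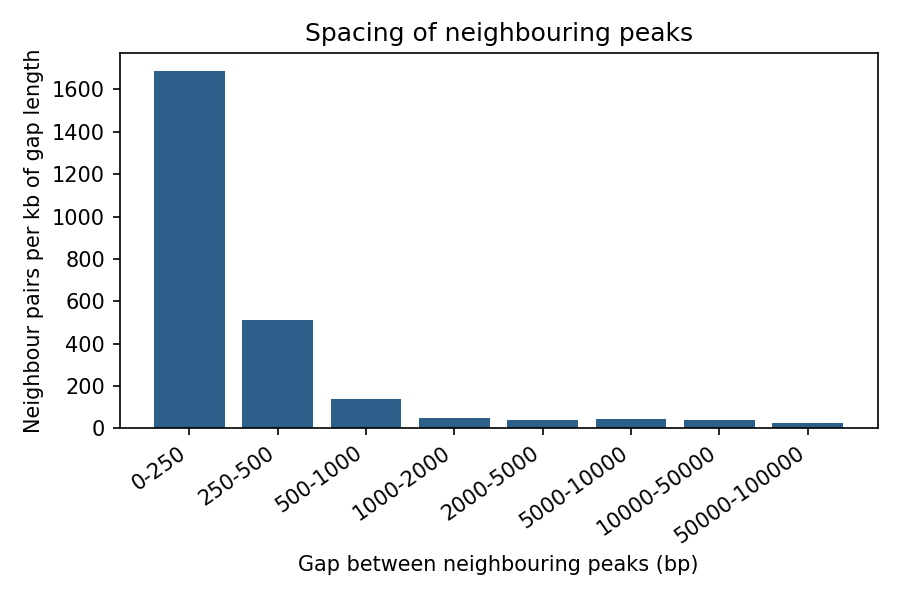
Number of neighbouring peak pairs per kb of gap length (vertical axis) in classes of the gap between them in bp (horizontal axis). The density is 1688 per kb for gaps under 250 bp and 46 per kb for gaps of 1000 to 2000 bp.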

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

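Alternatives using spans, gene numbers, 1 Mb bins, merging under 1 kb and, for chromosome X, the upper 25% of scores were chosen after the data were seen. The peak number fell from 7313 to 3657 and 1829 with the upper 50% and 25% of scores, by construction, and to 6693 with peaks under 1 kb apart merged, while merging overlapping or touching peaks left 7313. The ratio of chromosome X to autosomes per Mb, 0.272 with all peaks, was 0.154 with the upper 50% of scores, 0.0828 with the upper 25% and 0.388 per protein-coding gene, and stayed below 1 in each. The cluster number, 418, became 67 within 10 kb, 678 within 100 kb, 69 with the upper 50% of scores and 251 with peaks under 1 kb apart merged, whether placed uniformly or within 1 Mb bins. Each exceeded the average of random placements, which were not merged in turn. Of the 10 peaks ranked by score, 4 were among the 10 by width and 1 among the 10 by score per kb. The median width, 913 bp, became 1090 bp with the upper 50% of scores, 1241 bp with the upper 25% and 988 bp with peaks under 1 kb apart merged. The comparison of genotypes, gene features, motifs and gene lists, and chromosome lengths as expectation, were not run, because the peak list names no genotype and an mm9 genome or annotation was not used here. No paired analysis was possible because there was 1 library per group and 1 peak list. With read depth not given, a weak or absent peak does not show absent binding.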

Other observations

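The tests of gene number and score on chromosome X, of chance placement and of chromosome length were chosen only after the result was seen. The tests of peak width beside close neighbours and of receptor genes were set before their results were computed, except that matching widths on score, dealing receptor shares at random and leaving out chromosome 7 were added after.

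On chromosome 8, 3 of the 14 highest-scoring peaks lay within 236.7 kb of otherwise peak-poor sequence. This region and the cutoff of 14 were chosen after the values were seen. The 3 peaks were at 19784192 to 19785985 (score 799.01, rank 6), 19891692 to 19893815 (score 593.01, rank 14) and 20018833 to 20020873 (score 1023.8, rank 1), 105.7 and 125.0 kb apart. The nearest other peaks lay 936.9 kb before and 3149.7 kb after them, with scores of 127.07 and 112.08. Regions where reads do not map uniquely were not separated here either, so these scores do not rank binding strength. Unplaced sequences held 15 peaks with a median score of 83.0 and a highest score of 259.9, including 5 on 1 sequence of chromosome 9. Among scores that matched a Poisson background of 1, a k of 11, 15, 19 and 23 was held by 160, 89, 29 and 12 peaks, more than the 79, 27, 5 and 7 peaks at the next higher k. At backgrounds of 2 and 3, a k of 15, 19 and 23 also held more peaks than the k on either side. These were 61, 34 and 17 peaks at a background of 2, and 24, 24 and 14 at a background of 3. A k of 27 at a background of 3, with 3 peaks, did not. A plain count of tags gives no reason for an excess at the same k across backgrounds, which speaks against reading k as unscaled tags.

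Chromosome X held few peaks, and those it held scored low. A smaller number of genes is not enough as the whole cause, since X had 134.6 peaks per 1000 protein-coding genes (95% interval 112.4 to 159.8) against 261.1 on the lowest autosome. Whether each X locus gave a weaker signal, as a single X copy per cell would, cannot be told apart from other causes: the low median score on X, 87.7, is part of the pattern that prompted this explanation and is no separate test of it. A thinning of k by a factor of 0.5 in the 1503 autosomal peaks with a matched score kept 24.6% of them above the lowest score of the list with an unchanged background and 52.3% with a background reduced alike. These shares decide nothing, since they read k as tags over an unscaled background, which was not established, and cover only peaks with whole-number backgrounds. The excess at the same k across backgrounds, given above, speaks against reading k as unscaled tags. The sex of the animals is not given in the sources used here, and lower occupancy of X-linked genes in these cells would also lower both number and score and was not tested.

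Gaps under 1 kb between neighbours, 619 in number, exceeded placement at the local density in all of 1000 draws, so chance is not enough to account for them. One enriched region cut into pieces by the peak caller is a candidate explanation: peaks with a close neighbour were narrower (ratio of median widths 0.824) but also scored lower, and within deciles of score the ratio was 0.913 (permutation p = 0.0001, the smallest that the permutations can give, narrower in 10 of 10 deciles). The 590 regions formed by joining such peaks spanned a median of 1881 bp against 942 bp for the other peaks, which joining itself enlarges, so the pieces would have to come from regions wider than the usual peak. Adjacent but separate binding sites would give the same spacing. They could also give narrower peaks, since called peaks did not overlap and a close neighbour limits how far a peak extends. The width ratios therefore do not tell these explanations apart, and separate sites were not tested, which needs the read coverage.

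Differences in peak number between autosomes exceeded what length alone gives, with the densest autosome 2.43 times the sparsest per Mb (dispersion against 100000 random draws by span, a permutation-type test, p = 1e-05, the smallest that the draws can give). Chromosome 7, the lowest per gene, carries 417 of 1465 olfactory and vomeronasal receptor genes, families expressed mainly in sensory neurons. A hypothesis that peaks follow the genes other than these receptors was tested by leaving them out. The coefficient of variation of peaks per 1000 genes over the 19 autosomes fell from 11.1% to 8.37%, against a median of 12.9% when the receptor shares were dealt at random to the autosomes (one-sided permutation p = 0.0013). Without chromosome 7, which prompted the hypothesis, it fell from 9.25% to 7.97% (permutation p = 0.016). Chromosome 7 rose from 261.1 to 328.6, nearer the level of all autosomes (346.9 with and 373.3 without receptors), whereas chromosome 2, with 287 receptor genes, went from 337.3 to 402.0, farther from it. Of the 19 autosomes, 13 lay nearer that level without the receptors and the others farther from it. The level itself rose, so an autosome above it could come nearer with few or no receptor genes left out. Chromosome 12, with 0 receptor genes and 418.3 in both cases, was among the 13. This count is therefore no test of the hypothesis. Without the receptors, the relation of peaks to gene number had r = 0.96 against 0.93 with all genes, a difference that was not tested. Without the receptors the range was 311.5 (chromosome 14) to 428.3 (chromosome 19), and chromosome X stayed at 135.6.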
